A study of Homo sapiens with 13 samples.

How the data were processed

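Chromatin was measured in 13 samples of decidualized human endometrial stromal cells: H3K27ac ChIP-seq (2 samples), H3K4me3 ChIP-seq (2 samples with 75 bp reads and 2 with 36 bp reads), input chromatin (2 samples for each read length) and DNase-seq (3 samples, 2 biological replicates, 1 of them in 2 lanes). Per the submitters' processing notes, reads were handled with CASAVA 1.8.2 and Bowtie2 (version not stated) and mapped to hg19. The deposited files were 3 interval lists, 1 per assay, each pooled over replicates, with interval names of the peak caller MACS (version not stated). The score in each list is the peak caller's score per interval as deposited by the authors, in a column where MACS writes −10 times the log10 of a p value. No normalization between lists is stated, so scores were compared within a list only. The other deposited columns used are the interval start and end in bp. The labels name the same H3K4me3 list for both read lengths and do not say which libraries entered it. No read totals and no input signal were in the lists, so the depth per sample is unknown, and intervals printed here cover counting error only.

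The DNase list held 137108 intervals, the H3K4me3 list 22440 and the H3K27ac list 24336. Autosomal intervals were kept (133092, 21645 and 24018), because the cells were of human origin and sex chromosomes are not reported. The DNase intervals were numbered up to 275323, and the deposited list held 49.8% of that number. Why the other numbers are absent is not stated. Scores gathered at 3100, which 7757 H3K4me3 intervals (35.8%) reached or passed.

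The genome build was checked against GRCh37 with GENCODE 44 lifted to it. All DNase intervals ended inside their GRCh37 chromosome. In the H3K4me3 list 225 intervals, on chromosomes 3, 4 and 19, ended beyond it, and so did 71 H3K27ac intervals on chromosomes 3 and 19. Midpoints in GRCh37 assembly gaps numbered 0 for DNase, 412 for H3K4me3 and 265 for H3K27ac. Shifting each autosome in steps of 1000 bp, the share of midpoints within 1 kb of a start site was highest with no shift on 22 of 22 autosomes for DNase and on 0 of 22 for each histone list. Shifting raised the mean share from 7.89% to 34.6% for H3K4me3. The labels state hg19 for all samples, but both histone lists were in an earlier numbering. A conversion between numberings was not used here, so histone intervals were compared with each other, with genes only by their numbers per autosome, and not with sequence or DNase intervals. This left out promoter location, gene lists and motifs for the histone marks, combined promoter states, distal H3K27ac intervals with open chromatin, and gene names at H3K27ac clusters and wide H3K4me3 intervals. Repeat content was left out because the reference sequence had 0 lower-case bases, which would mark repeats.

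The groups, tests, alternatives, 14 gene lists (307 genes, 306 matched in the annotation, 2 of them renamed; PECAM1 was not matched) and 22 motif consensus sequences were chosen before the data were examined. The rule for named genes was also fixed then. It takes the decidual markers, steroid receptors and coregulators, and endometrial stromal transcription factors by count with examples in list order. Of every other list it takes at most 4 members with and 4 without an interval, in list order. It also takes the 3 intervals with the highest score in each list, and the longest clusters and widest intervals by position. The comparison of distal intervals around gene lists, the split of H3K27ac by overlap, the density per autosome, the HOXA11 values and the recurrent sequence were added after the data had been seen.

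Overlap was the share of intervals with at least 1 bp in the other list, against 1000 random placements within the same chromosome (bedtools 2.31.1, fixed seeds), with a one-sided permutation p. As no sequence of the earlier build was at hand, chromosome ends were set by the last interval and gaps were not excluded for the histone lists. For DNase, runs of at least 100 unknown bases were excluded. Widths of intervals with and without the other mark were compared with 100000 permutations of their medians, two-sided, and with the widths of intervals that overlapped after random placement. Overlap per class of score or width was set against placement of the same class; both were added after the data had been seen. Promoters were 1000 bp on either side of any annotated start site of 19222 autosomal protein-coding genes. The location of DNase intervals used 100 further placements for exons, introns and intergenic sequence, in that order of priority after promoters. Gene lists were compared with all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 14 lists. They were also compared, two-sided, with 10000 random lists matched in 20 bins of promoter GC content, taken around the canonical start site. CpG-rich promoters had observed over expected CpG of 0.6 or more and GC of 55% or more. Distal intervals within 50 kb of a gene were compared in the same way, with genes matched in GC content of the region and number of close neighbours. Motifs were counted on both strands in 200 bp windows around interval midpoints, against windows 5000 to 10000 bp away matched in bins of 5 percentage points of GC, by Fisher's exact test, two-sided. Windows that overlapped a DNase interval were left out of these flanks. Adjustment ran over the motifs of promoter, distal and all intervals. Matching kept 67794 of 103324 distal intervals, 12337 of 29768 promoter intervals and 80066 of all 133092. Shares have exact (Clopper-Pearson) 95% intervals, and ratios have normal intervals on the log scale. The threshold was an adjusted p of 0.05. Correlations across autosomes used 100000 permutations, two-sided. Score excess is the log10 score minus the value of a straight line fitted to log10 width over all DNase intervals.

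The settings varied by design were other overlap rules, a stricter score, local placement, promoter windows of 500 and 2500 bp, GC-matched genes, motif windows of 400 bp and flanks without GC matching. Alternatives added after the data had been seen were a score of at least 50 in both histone lists, local placement for promoter location, the canonical start site alone, leaving out the widest 10% of DNase intervals, the consensus read backwards, low-copy windows, FOXO without the recurrent sequence, better-scoring and nearer distal intervals, and other copy-number bounds. The methods were tested on simulated data. A planted overlap of 20% was recovered as 21.1%, and lists drawn from GC-poor promoters were called by Fisher's exact test in 54 to 84% of cases but in 1.5 to 4% by the matched comparison. In that simulation openness depended only on GC content around the canonical start site, the same quantity that was matched. It therefore does not test the matched comparison where any start site counts as open. Computing used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, numba 0.67.0, samtools 1.23.1 and matplotlib 3.10.9.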

Results

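The series profiled chromatin in cultured human endometrial stromal cells that had been decidualized, the change that prepares the uterine lining for implantation. The cells were treated with 0.5 mM 8-Br-cAMP, a stable cAMP analogue, and medroxyprogesterone acetate, a synthetic progestin given in the labels as 1 mM, for 48 to 72 hours at passages 6 to 10. The 13 samples formed 6 groups. H3K27ac ChIP-seq, a mark of active promoters and enhancers, had 2 samples. H3K4me3 ChIP-seq, a promoter mark, had 2 samples with 75 bp reads and 2 with 36 bp reads. Input chromatin had 2 samples with each read length. DNase-seq, which maps open chromatin, had 3 samples from 2 biological replicates. There was no untreated group, so no effect of decidualization was measured. Values came as 1 interval list per assay, pooled over replicates, so no value below has a spread between replicates. Read totals per sample were not given, so the depth is unknown. The DNase list held 133092 autosomal intervals over 129.9 Mb, with a median width of 644 bp (quartiles 476 and 1084). The H3K4me3 list held 21645 intervals over 32.1 Mb, with a median width of 1348 bp (quartiles 765 and 1928). The H3K27ac list held 24018 intervals over 15.6 Mb, with a median width of 464 bp (quartiles 289 and 821). The lowest score of the peak caller was 50 in the DNase list, 50.12 in the H3K4me3 list and 30 in the H3K27ac list, and 67% of the H3K27ac intervals scored below 50. The DNase positions were those of GRCh37, but both histone lists used an earlier numbering of the genome. Gene names and sequence are therefore given for DNase intervals only.

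The first comparison asked where open chromatin lay relative to genes. In these stromal cells, DNase intervals were more frequent at gene starts and in coding sequence than at random. They were somewhat less frequent in introns and between genes, which together held most of them. Of the DNase intervals, 29768 (22.4%, 95% exact interval 22.1 to 22.6) lay within 1 kb of a start site of a protein-coding gene. Random placement on the same chromosome gave a mean of 7.57%, a 2.95-fold difference (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Coding exons outside promoters held 4.68% of intervals against 0.895% at random, a ratio of 5.23. Introns held 33.3% against 39.1%, and intergenic sequence held 37.2% against 50.6%, ratios of 0.852 and 0.736. The highest score, 3233, though 637 intervals reached 3100, where scores gather and their order says little, belonged to 19:24183417–24187073, which lay 29134 bp from the nearest start site, that of the zinc finger gene ZNF254. The interval 16:88955031–88964709 (score 3228) lay 4214 bp from a start site of CBFA2T3, a transcriptional corepressor. The interval 8:145537454–145546820 (score 3225) covered a start site of DGAT1, an enzyme of triglyceride synthesis. The intervals were rich in G and C, with a median of 57.1% in intergenic sequence against 40.2% at random. Placement within 500000 bp of the original position, which keeps the local gene density, lowered the promoter difference to 1.92-fold (11.6% at random). No placement was matched in GC content, and the coding-exon ratio had no local control. Of the widest 10% of intervals, 33.3% lay within 3 Mb of a chromosome end, against 5.00% of all intervals placed at random. What GC content or chromosome ends contribute to these differences was not tested.

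The next comparison asked which genes had open promoters, counted as open when a DNase interval lay within 1 kb of any annotated start site. Of 19222 autosomal protein-coding genes, 15282 (79.5%, 78.9 to 80.1) were open. Promoters rich in CpG dinucleotides were open in 93.2% of 11584 genes (92.7 to 93.6), and other promoters in 58.7% of 7638 genes (57.6 to 59.8). Endometrial stromal transcription factors were all open, 28 of 28 (100%, 87.7 to 100), against 79.5% of the other genes (Fisher's exact test, two-sided, p = 0.00344, adjusted p = 0.0161 over 14 gene lists). The list held HOXA9 (interval score 519), HOXA11 (score 3100) and HOXA13 (score 546), homeobox factors that pattern the female reproductive tract. HOXA10, which is needed for implantation, had a single interval of score 50, the lowest in the list, at an alternative start (7:27219023–27219383). Random gene lists matched in promoter GC content were open at 81.6% on average, and the stromal factors were above them (two-sided permutation p = 0.0006, adjusted p = 0.0084). GC content was matched around the canonical start site, while any start site could count as open. The number of start sites per gene was not matched. Neighbours can share an interval, as STAT5A and STAT5B did (17:40439925–40441777). The random lists drew each gene separately, so the permutation p may be too small. Counted at the canonical start site alone, 22 of the 28 genes were open. The 6 others were HOXA10, WT1, STAT5B, TCF7L2, RUNX1 and RUNX2, and the difference from other genes fell from 20.5 to 5.41 points (exact adjusted p = 0.782). Without the widest 10% of intervals it fell to 9.26 points (22 of 28; exact adjusted p = 0.644).

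Decidual markers were open at 20 of 22 genes (90.9%, 70.8 to 98.9), 11.4 points above other genes (Fisher's exact test, adjusted p = 0.403), which turned to −1.15 points without the widest 10% of intervals (15 of 22 open; exact adjusted p = 1). PRL, the prolactin gene whose expression the submitters followed as a marker of decidualization, had no interval within 1 kb of an annotated start site. STC1, a secreted regulator of mineral balance, had none either. Starts missing from the annotation were not examined, and a promoter without an interval is not shown to be closed. IGFBP1, the IGF-binding protein secreted by decidual cells, had an interval at 7:45927801–45929111 with a score of 488. FOXO1, a transcription factor that switches on decidual genes, had one at 13:41238800–41241952 (score 903), and HAND2, a progesterone-induced stromal factor, had one at 4:174449678–174451654 (score 506). The signalling genes WNT4 (score 560) and BMP2 (score 574) were open too. Steroid receptors and coregulators were open at 15 of 15 genes (100%, 78.2 to 100; Fisher's exact adjusted p = 0.105), and passed the threshold with the better-scoring intervals alone (exact adjusted p = 0.0465). Lists matched in promoter GC content were open at 91.7% (permutation adjusted p = 0.792), and without the widest 10% of intervals 11 of the 15 genes were open (exact adjusted p = 1). The progesterone receptor gene PGR had an interval at 11:100997866–101000195 (score 901) and the oestrogen receptor gene ESR1 had one at 6:152128402–152129899 (score 551). ESR2 (score 395) and the glucocorticoid receptor gene NR3C1 (score 354) were open as well.

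Genes of the cAMP pathway, through which the cells were stimulated, were open at 22 of 22 (Fisher's exact adjusted p = 0.0385). They included the protein kinase A subunits PRKACA (score 253), PRKACB (score 444), PRKAR1A (score 574) and PRKAR2B (score 522). Epithelial markers were open at 22 of 22 as well (exact adjusted p = 0.0385), among them EPCAM (score 530), CDH1 (score 538), KRT7 (score 655) and KRT8 (score 305). Hepatocyte markers were open at 5 of 18 (27.8%, 9.69 to 53.5; exact adjusted p = 4.66e-05), with ALB, APOA2, APOB and TTR among those without an interval and APOA1 (score 845) and SERPINA1 (score 81) among those with one. Trophoblast markers were open at 8 of 17 (47.1%, 23 to 72.2; exact adjusted p = 0.0161). GCM1, ERVW-1, ERVFRD-1 and CGA had no interval, while CGB5 (score 959) and GATA3 (score 105) did. Against lists matched in promoter GC content, none of these 4 lists passed the threshold. The cAMP pathway lay 8.39 points above matched lists (permutation adjusted p = 0.358), in place of 20.5 above other genes, and epithelial markers 9.87 (adjusted p = 0.429) in place of 20.5. Hepatocyte markers were at −20.5 points (permutation adjusted p = 0.273) in place of −51.8, and trophoblast markers at −18.6 (adjusted p = 0.358) in place of −32.5. The cAMP pathway and epithelial markers also lost their calls with a 2500 bp window (17.1 points for both), at the canonical start site alone (17.8 and 13.2 points) and without the widest 10% of intervals (12.5 points for both). Epithelial markers lost theirs in the better-scoring part of the intervals (18.9 points), and trophoblast markers at the canonical start site (−26.1 points).

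The remaining 7 lists did not pass the threshold. Stromal and matrix genes were open at 25 of 32 (exact adjusted p = 0.827), with COL1A1 (score 693) and COL1A2 (score 276) open and COL3A1, COL5A2, VIM and DCN not. Cytokines, growth factors and prostaglandin enzymes were open at 25 of 32 (exact adjusted p = 0.827), with LIF (score 654) and IL6 (score 58) open and CXCL8, CCL2, ANGPT1 and ANGPT2 not. Ubiquitously expressed genes were open at 23 of 24 (exact adjusted p = 0.103) and proliferation genes at 19 of 20 (adjusted p = 0.174). The genes without an interval there were RPLP0, a ribosomal protein, and CCNA2, a cyclin. Endothelial markers were open at 11 of 15 (exact adjusted p = 0.65), haematopoietic markers at 14 of 21 (adjusted p = 0.267) and neuronal markers at 16 of 18 (adjusted p = 0.65). Among genes that mark blood cells, CD8A (score 859), CD14 (score 391), CD19 (score 53) and CD68 (score 158) had an interval, and PTPRC, CD3D, CD3E and CD4 had none.

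**Figure D1:**
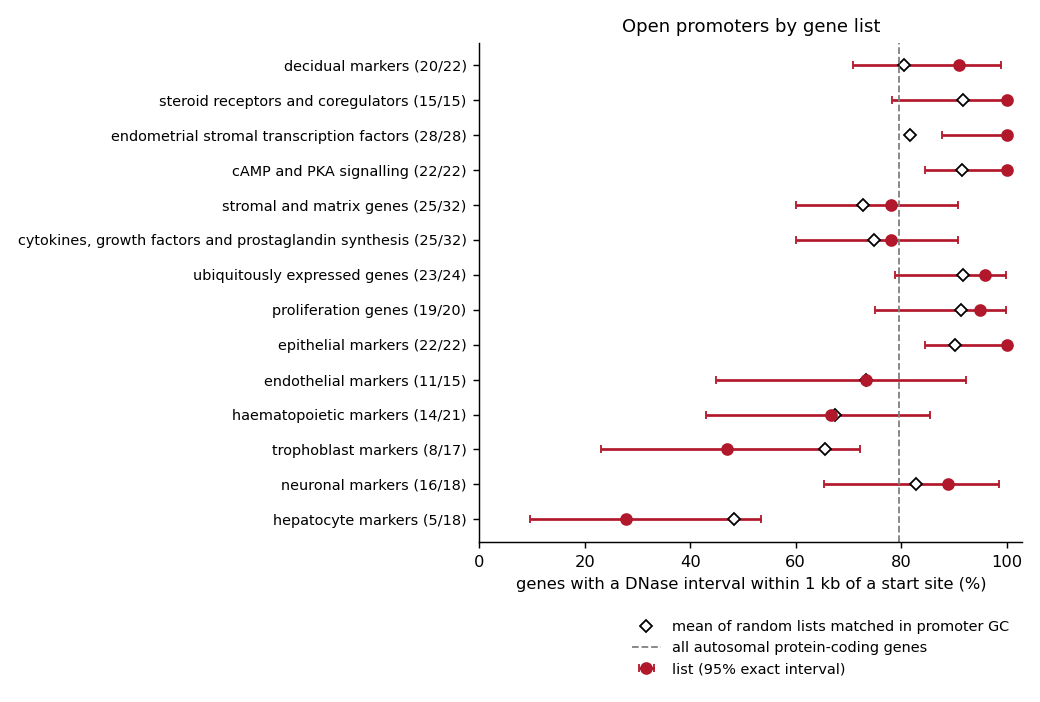
Share of genes with a DNase interval within 1 kb of a start site (%, horizontal axis) for each of 14 gene lists, with the open and total genes in brackets; red points are the lists with 95% exact intervals, open diamonds the mean of random lists matched in promoter GC content, and the dashed line all 19222 genes. The stromal transcription factors (100%) sit above their matched lists (81.6%) by more than their interval, with any start site counted. Matching used GC content around the canonical start site and drew each gene separately. Hepatocyte markers (27.8%) sit below the dashed line and below their matched lists (48.2%), the latter without passing the threshold after adjustment.

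HOXA11, a homeobox gene that maintains uterine stromal identity, lay under the highest-scoring DNase signal within 30 kb, which the data do not tie to the genomic copy of the gene. The interval 7:27223889–27225835, over its start site, scored 3100, the value at which scores gather, and thus at least 5.49 times the value usual for its width. The neighbouring interval 7:27222383–27223398, over its last coding exon, scored 1935, or 8.25 times the usual value. The other 16 intervals within 30 kb scored close to the usual value, with a median log10 excess of 0.0118 (range −0.112 to 0.167). The intervals scoring 3100 and 1935 covered all 3 coding parts of HOXA11 and 65.4% of the bases between them, but 2.13% of its 3′ untranslated part, and the HOXA11 signal was singled out after its values were seen.

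**Figure D2:**
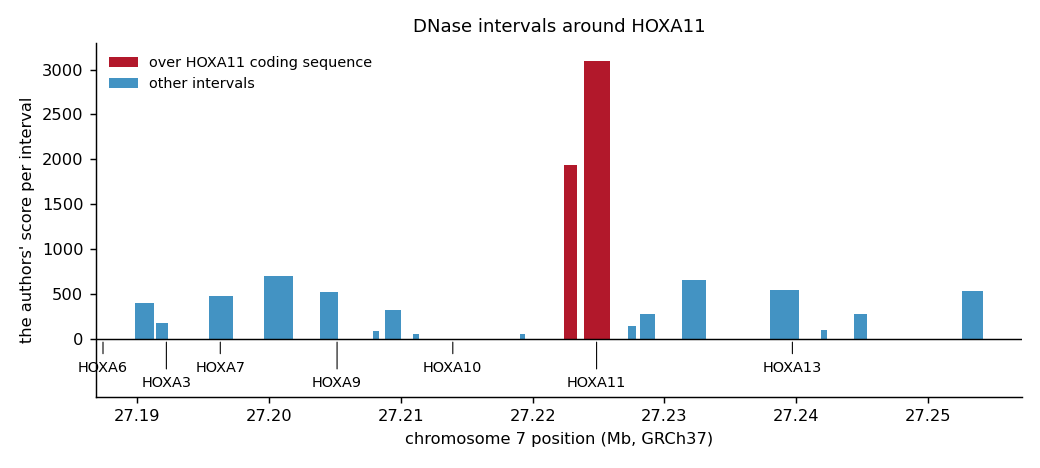
The authors' score (vertical axis) of each DNase interval within 30 kb of HOXA11 by position on chromosome 7 (Mb, GRCh37, horizontal axis), with bar width equal to interval width and canonical start sites of HOXA genes marked below the axis. The 2 red intervals over HOXA11 coding sequence reach 1935 and 3100, far above the blue ones, and HOXA10 has no interval at its canonical start.

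Distal open chromatin was compared around the same lists, as the number of DNase intervals over 1 kb from every start site and within 50 kb of a gene. Endometrial stromal transcription factors had 7.75 such intervals per gene (SD 6.03 over 28 genes). Genes matched in GC content of the surrounding region had 6.22, and the difference did not pass the threshold (two-sided permutation, adjusted p = 0.334 over 14 lists). Counting better-scoring intervals alone gave 4.5 against 2.61, a ratio of 1.72 (permutation adjusted p = 0.014), and counting within 20 kb gave 3.71 against 2.43, a ratio of 1.53 (adjusted p = 0.028). Neighbours in this list, such as HOXA9, HOXA10, HOXA11 and HOXA13, share distal intervals, which were then counted more than once. The random lists drew each gene separately, so both p values may be too small. Decidual markers had 7 per gene against 6.12 (permutation adjusted p = 0.449), with 1 around PRL (median of its matched genes 1), 6 around IGFBP1 (3), 2 around FOXO1 (3) and 10 around HAND2 (3). None of the 14 lists passed the threshold with all distal intervals. Across genes, which are not independent replicates, the count of distal intervals rose with the GC content of the region (Spearman's rho 0.837).

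The motif comparison asked which factors' consensus sequences were frequent in open chromatin, relative to windows 5 to 10 kb away with the same GC content. GC matching kept 67794 of the 103324 distal intervals, and the GC-matched values cover these only. They held more FOXO and MEF2 consensus sequences and fewer of 8 others, of which only TEAD and NF-Y stayed less frequent in the better-scoring intervals. The 8 were STAT, GATA, NF-Y, TEAD, AP-1, RUNX, TWIST/HAND and the progesterone and glucocorticoid receptors. The FOXO motif, bound by the decidual factor FOXO1, occurred in 2.01% of 67794 distal windows against 1.08% of flanks, a ratio of 1.87 (1.71 to 2.05; Fisher's exact test, two-sided, adjusted p = 2.74e-43). MEF2, a muscle and mesenchymal factor motif, had a ratio of 1.66 (1.34 to 2.05; exact adjusted p = 1.15e-05), a call lost in the better-scoring intervals (1.07) and in low-copy windows (1.44) and turned without GC matching (0.458). STAT had the lowest ratio of the 8 that were less frequent, 0.593 (0.536 to 0.657), and RUNX the highest, 0.867 (0.785 to 0.958). In the better-scoring intervals TEAD was at 0.838 and NF-Y at 0.763, but STAT (0.874) and AP-1 (0.977) lost their calls, and GATA (1.12), RUNX (1.10) and TWIST/HAND (1.03) turned without passing the threshold. The receptor element, read by PGR, had a ratio of 0.729 (0.592 to 0.899; exact adjusted p = 0.00937), but of 0.980 in low-copy windows, 1.13 in the better-scoring intervals and 1.17 without GC matching, none past the threshold. AP-1 had a ratio of 0.835 (0.784 to 0.889) and CTCF one of 0.864 (0.696 to 1.07; exact adjusted p = 0.311), which turned to 3.80 (3.02 to 4.79; adjusted p = 3.29e-36) without GC matching. The cAMP response element, read by CREB, was at 1.32 (1 to 1.75; exact adjusted p = 0.111). The liver control motif HNF4 did not pass the threshold (0.860, 0.687 to 1.08) but was less frequent in 400 bp windows (0.736, 0.632 to 0.857; exact adjusted p = 0.000202), and the neuronal control REST occurred in 2 windows against 6. Of the 1365 distal windows with a FOXO motif, 647 held 1 recurrent 13-base sequence, and without these windows the FOXO ratio was 1.04 (0.935 to 1.15; exact p = 0.504). In windows of low-copy sequence FOXO stayed more frequent, at 1.39 (1.24 to 1.56; exact adjusted p = 7.69e-07), as were the cAMP response element (1.85), NRF1 (2.10) and the posterior HOX motif (1.12), while STAT (0.770) was the 1 less frequent motif and AP-1 was at 0.975 (0.905 to 1.05). CpG content was left unmatched, and the cAMP response and NRF1 consensus sequences hold CpG. Before GC was matched again, low-copy distal windows held 5.86 CpG on average against 4.12 in low-copy flanks. FOXO turned to 0.676 without GC matching. The same consensus sequences read backwards gave 1 more frequent and 9 less frequent in distal windows. Backwards STAT (0.585), TEAD (0.650), GATA (0.656) and AP-1 (0.716) had ratios as low as the forward ones or lower, so the low ratios of these 4 are not specific to the factors' motifs. Backwards NF-Y (0.811, forward 0.739) and TWIST/HAND (0.848, forward 0.831) were less frequent too, so their low ratios are at least partly unspecific.

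In promoter intervals, motifs known from promoters of widely expressed genes were more frequent than in flanks; the difference from distal intervals was not tested. ETS was at 4.33 times the flank share (2.70 to 6.96; exact adjusted p = 8.49e-11), NRF1 at 3.64 (1.87 to 7.08; adjusted p = 0.000195) and the cAMP response element at 3.07 (1.68 to 5.61; adjusted p = 0.000454). NF-Y was at 1.57 (1.28 to 1.92) and SP/KLF at 1.55 (1.30 to 1.85). TEAD (0.812, 0.691 to 0.955) and the TWIST/HAND E-box (0.812, 0.746 to 0.885) were less frequent, but not in the better-scoring intervals (0.921 and 1.01). Read backwards, 1 consensus was more frequent and 1 less frequent. The former was SP/KLF, whose consensus is the same in both directions, so the SP/KLF ratio has no such control. GC matching kept 12337 of the 29768 promoter windows and left CpG content unmatched, at 8.02 per window against 4.93 in flanks, and the NRF1, ETS and cAMP response consensus sequences hold CpG.

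**Figure D3:**
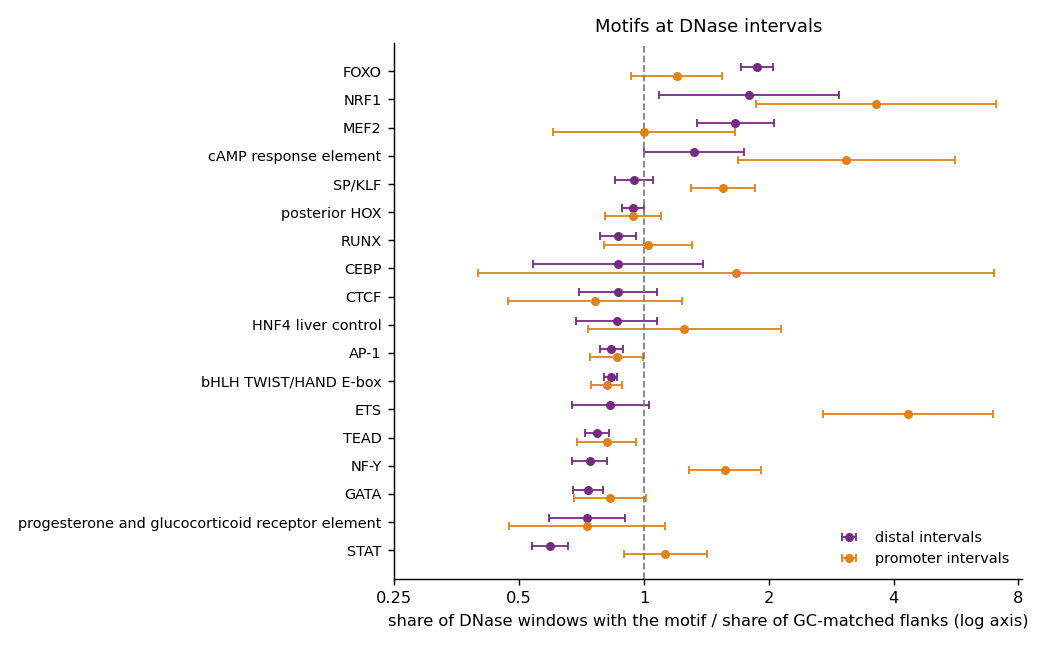
Ratio of the share of DNase windows with each motif to the share of GC-matched flanks (log axis, dashed line at 1) for distal (purple) and promoter (orange) intervals, with 95% intervals, for the 18 of 22 motifs that occurred in at least 50 distal windows and flanks together. FOXO stands highest among distal ratios (1.87) and ETS among promoter ratios (4.33).

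The last comparison asked how far the promoter mark H3K4me3 and the activity mark H3K27ac shared regions. Between 22.3% and 23.8% of each list did, far more than at random. H3K4me3 intervals overlapped H3K27ac in 4832 cases (22.3%, 21.8 to 22.9), against 1.73% at random, a 12.9-fold difference. H3K27ac intervals overlapped H3K4me3 in 5719 cases (23.8%, 23.3 to 24.4), against 1.70% at random, a 14-fold difference. Both one-sided permutation p values were 0.001 (adjusted p = 0.001 for both orders of the pair), the smallest that 1000 placements can give. Shared regions were wide: H3K4me3 intervals with H3K27ac had a median width of 1900 bp against 1152 bp for those alone, and H3K27ac intervals with H3K4me3 had 839 bp against 381 bp (two-sided permutation p = 1e-05 for both, the smallest that 100000 permutations can give). Wide intervals meet others more often by chance, but H3K4me3 and H3K27ac intervals that overlapped after random placement had median widths of 1646 and 614 bp on average, below the observed values (one-sided permutation p = 0.001 for both, the smallest possible). The overlap climbed from 10.5% in the lowest-scoring 10% of H3K27ac intervals to 46.5% in the highest, and from 4.53% in the narrowest 10% of H3K4me3 intervals to 48.6% in the widest. Against random placement of the same class, this was 7.51-fold and 18.3-fold for H3K27ac scores, and 4.54-fold and 16.0-fold for H3K4me3 widths. The narrowest 10% of H3K27ac intervals overlapped H3K4me3 no more than at random (1.12% against 1.18%; one-sided permutation p = 0.632). The 18299 H3K27ac intervals without H3K4me3 lay a median of 43.4 kb from the nearest H3K4me3 interval, and 45.5% lay over 50 kb away. Within 20 kb of H3K4me3 lay 32.1% of the highest-scoring 20% of them against 20.9% at random, and 29.0% of the lowest-scoring 20% against 20.2% (one-sided permutation p = 0.001 for both); the others were not compared. Placement within 500000 bp gave 7.40-fold for H3K4me3 and 8.23-fold for H3K27ac. With a score of at least 50 in both lists, 37.6% of H3K27ac and 12.8% of H3K4me3 intervals overlapped.

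**Figure D4:**
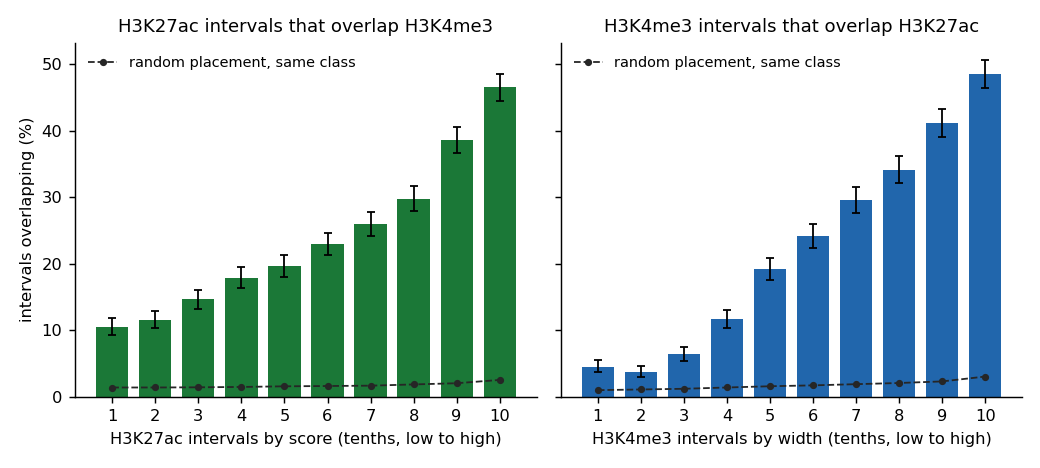
Share of intervals that overlap the other mark (%, vertical axis) in 10 equal classes of H3K27ac score (left, green) and of H3K4me3 width (right, blue), with 95% exact intervals; the dashed line is the mean of random placement of the same class. The share runs from 10.5% to 46.5% with H3K27ac score and reaches 48.6% in the widest H3K4me3 intervals.

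Across the 22 autosomes, H3K4me3 density followed gene density. H3K4me3 intervals per Mb had Pearson's r = 0.987 and Spearman's rho = 0.962 with protein-coding genes per Mb (permutation p = 1e-05 for each, the smallest possible). The value was r = 0.920 without the 2 autosomes farthest from the median gene density. H3K27ac intervals that overlapped H3K4me3 had r = 0.977 and rho = 0.968 (permutation p = 1e-05 for each), and r = 0.924 without those 2 autosomes. For H3K27ac intervals without H3K4me3 no relation was detected (r = −0.0971, permutation p = 0.667; rho = 0.00169, p = 0.996). Splitting H3K27ac by overlap with H3K4me3 itself ties the overlapping part to gene density, and the difference between the parts was not tested. Over all H3K27ac intervals r was 0.579 and rho 0.503 (permutation p = 0.0223 and 0.0185, adjusted p = 0.039 and 0.0323), but without the 2 autosomes r was 0.322 and rho 0.350, and neither passed the threshold (permutation p = 0.166 and 0.131). DNase intervals had r = 0.905 and rho = 0.819 (permutation p = 1e-05 and 2e-05), with r = 0.743 without the 2. In all, 7 relations were computed, and the adjusted p for r was 2.33e-05 for H3K4me3, for H3K27ac with H3K4me3 and for DNase.

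H3K27ac intervals within 12.5 kb of each other formed 14528 clusters, of which 66.8% held 1 interval and 566 held 5 or more (232 with a joining distance of 5000 bp, where the longest cluster stayed the same and the next ones were others). The longest by summed width lay at 11:64994757–65033240, in the numbering of the deposited list, with 7 intervals and 31778 bp. The next were 19:50618720–50674563 (8 intervals, 23782 bp) and 9:112666122–112751353 (33 intervals, 22251 bp), the last without any H3K4me3 interval. Of the 10 longest clusters, 7 overlapped H3K4me3. The highest H3K27ac scores were 1788.32 at 11:64941253–64949923, 1385.23 at 1:45044660–45048351 and 1232.22 at 11:65008030–65019091, which lay inside the longest cluster. The widest H3K4me3 intervals were 1:2590403–2612246 (21844 bp), 19:41473478–41492930 (19453 bp) and 1:226837134–226850829 (13696 bp). The highest H3K4me3 score, 3233.06, was shared, above the 3100 where scores gather, by 20:37023696–37025285, 17:78267328–78268881 and 22:38257664–38259181. No test was made on these rankings, and no gene is named because the lists were not in the numbering of the annotation.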

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

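Added after the data had been seen were the settings with a score of at least 50, the canonical start site, no widest 10%, better-scoring or nearer distal intervals, the consensus read backwards, low-copy windows and no recurrent sequence. The overlap of H3K4me3 and H3K27ac (10.7% to 37.6% over all alternatives) and the promoter share of DNase intervals (18.9% to 32.6%) stayed above random under every alternative run. Joining at 5000 bp gave 17462 H3K27ac clusters in place of 14528, and 232 of 5 or more intervals in place of 566, as a shorter distance joins fewer. Of 14 gene lists, 5 passed the threshold; 3 did with 2500 bp, 1 with GC matching, 1 at the canonical start site and 2 without the widest 10% of intervals. Of the distal lists, 0 passed, but 1 did with better-scoring intervals and 1 within 20 kb. Of 84 single gene-list values, 63 kept direction and side, 14 weakened, 1 (steroid receptors, better-scoring intervals) strengthened and 6 reversed. The reversed differences from other genes, in percentage points, were 0.533 for both stromal and matrix genes and cytokines with 500 bp, 5.37 and 3.35 for these with GC matching, 1.83 for cytokines at the canonical start site, and −1.15 for decidual markers without the widest 10%. More frequent motifs in distal windows numbered 5 without GC matching, 1 in the better-scoring part, 1 read backwards and 4 in low-copy windows, and less frequent ones 2 in the better-scoring part and 1 in low-copy windows. In promoter windows, 10 were less frequent without GC matching, 0 in the better-scoring part and 1 read backwards, where 1 was more frequent. In all windows, 11 were less frequent without GC matching; the better-scoring part gave 3 more and 1 less frequent, and backwards reading gave 2 more frequent. Of 83 named motif values, 49 kept direction and side, 17 weakened and 17 reversed. Reversed log2 ratios in distal windows without GC matching were −0.57 for FOXO, −1.13 for MEF2, 0.23 for the progesterone and glucocorticoid receptor element and 1.93 for CTCF, where the windows compared differ in GC content by construction. In the better-scoring part they were 0.17 for GATA, 0.14 for RUNX, 0.0439 for the E-box (0.0147 in promoters) and 0.17 for the receptor element. Read backwards they were 0.68 for CTCF, −0.24 for FOXO, −0.81 for MEF2, 0.00831 for the receptor element and −0.29 for the cAMP response element in promoters. In low-copy windows they were 0.14 for CTCF, 0.13 for RUNX and 0.0262 for the E-box. For these changes the cause was not tested, except that fewer windows or start sites were counted in the better-scoring, low-copy and canonical settings. FOXO without the recurrent sequence fell to a log2 ratio of 0.05. Backwards NRF1 in promoters gave no ratio. Alternatives set in advance but not run, for want of a shared build or marked repeats, were those of combined promoter states, distal H3K27ac with open chromatin and repeat content, and the histone part of promoter location, gene lists and motifs. No paired analysis was possible because each list pools its replicates, and no replicate could be left out. The unknown depth limits what the lists leave out: a promoter without an interval is not shown to be closed.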

Other observations

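The tests of LINE-1 sequence, of GC content alone, of copies with repeated surroundings, of AP-1 and CTCF and all those of HOXA11 were chosen only after the result was seen, as were the counts of HOX genes, Alu sequence and high-copy windows; the tests of shared reads and of GC content in 100 kb windows were written before their results. DNase intervals away from promoters held more windows of high-copy sequence, such as transposable elements and other repeats, than their flanks. The median window differed little (41 against 37 copies). Whether reads were placed uniquely is not stated, so these values do not show that the repeats were open. Of the 67794 distal DNase windows kept by GC matching, 37% (36.6 to 37.4) were made of 14-base words with a median of at least 200 copies, against 17.6% (17.4 to 17.9) of GC-matched flanks, a ratio of 2.10 (1.97 at 100 copies and 2.21 at 500). The core sequence CCAGCACTTTGGGAGGC of Alu elements, the most numerous primate retrotransposons, lay in 8477 distal windows (12.5%) against 3224 flanks (4.76%), an odds ratio of 2.86. High-copy windows without either this sequence or the recurrent FOXO sequence still made up 24.3% of distal windows and 13.7% of flanks. High-copy distal windows held 9.35 CpG dinucleotides on average against 5.88 in high-copy flanks, and the other distal windows 5.86 against 4.12.

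HOX genes, which set position along the body axis and were again chosen after their values were seen, were open at 34 of 39 (87.2%), against 79.5% of all genes, a difference that was not tested. The 5 without a DNase interval were HOXB13, HOXC9, HOXC12, HOXD1 and HOXD13. The gene with the most distal intervals nearest to its start site within 100 kb was ADRA2C, an adrenergic receptor gene, with 81. It was followed by ADAMTS2, a procollagen-processing enzyme (68), PDGFA, a growth factor for mesenchymal cells (67), PSAPL1 (64) and CASZ1, a zinc finger factor (62). The region around ADRA2C had a GC content of 56.5% and that around PDGFA 58.0%, against a median of 39.9% over all 100 kb windows. These counts were not matched in GC content and can be higher where the next gene is far, so they are not densities.

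The recurrent sequence CTTTGTTTACCTA, which holds a FOXO motif, had 5169 autosomal copies, of which 1871 (36.2%, 34.9 to 37.5) lay in DNase intervals, against 1.30% of positions 5 to 10 kb away. A start sequence of LINE-1 ORF1 was first searched in the orientation as written, where it was near 3 copies, and then, after that negative result, in the other, where it lay within 1500 bp of 24.7% of copies against 0.0967% of positions away, so some copies may be LINE-1 5′ ends. With GC content matched in bins of 5 percentage points, distal windows held the sequence 21.6 times as often as flanks (lower bound 15). That argues against GC content alone for the windows kept, but not against CpG content, which was unmatched. The sequence was chosen after the data had been seen, and flanks that overlapped a DNase interval were left out. The ratio may therefore be too high. Copies with nearly unique surroundings lay in DNase intervals 11 times as often as positions away (lower bound 9.85). This met the bound set beforehand against shared reads as the whole cause. However, positions away were not matched in GC content, whose median around the copies was 59.2%. Uniqueness was also counted on exact 75-base stretches only, so shared reads as the whole cause are not excluded. For copies with repeated surroundings, shared reads and open chromatin cannot be told apart: 72.6% of LINE-1-marked copies were in intervals when surroundings were repeated and 16.7% (8 of 48) when nearly unique, and repeated surroundings also mark young copies. No biological explanation was tested, because the design has no group without decidualization.

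DNase intervals away from promoters were rich in G and C. In 6990 windows of 100 kb, each over 100 kb from every start site, the number of intervals rose with GC content. Spearman's rho was 0.340, between the bounds of 0.5 and 0.2 set beforehand. Rho does not give the size of this rise. Among equal classes of GC content, these windows held 0.745 intervals on average in the lowest class and 7.48 in the highest. Over all windows of 100 kb, rho was 0.751, with 0.794 intervals in the lowest class and 22.5 in the highest. By the bounds set, an effect of GC content on which regions were called cannot be told apart from open chromatin that is itself GC-rich. An AP-1 consensus in the middle 200 bp of most distal intervals is argued against, for the 67794 of 103324 distal intervals that GC matching kept. Sequence farther from the midpoint was counted only in 400 bp windows (ratio 0.817), and sites other than the consensus were not counted. The ratio to GC-matched flanks was 0.835, but the reversed consensus was low too (0.716). The low ratio itself thus does not count against AP-1. What argues against AP-1 in most intervals is that the forward ratio was only 1.17 times the reversed one (1.06 to 1.29). As that value lies above 1, a smaller contribution is left open. In low-copy windows (0.975, 0.905 to 1.05) and better-scoring intervals (0.977, 0.882 to 1.08) the ratio was not shown to lie below 1, but no upper bound passed 1.08. For CTCF the ratio of 0.864 (0.696 to 1.07) rested on 153 windows, includes 1 and turned to 3.80 (3.02 to 4.79) without GC matching, so a contribution cannot be told apart from none. No biological explanation beyond these motifs was tested, because the design gives no group to compare.

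The 2 DNase intervals over HOXA11 scored far above others of their width. Extra copies of the HOXA locus are argued against, as the other intervals within 30 kb had a median log10 excess of 0.0118. An unusually open promoter cannot be told apart from other causes, as the interval away from every HOXA11 start site, with an excess of 0.917 (99th percentile of all intervals, 0.355), is itself part of the pattern. HOXA11 coding sequence from outside the genome, such as a cDNA or a plasmid, cannot be told apart from the genomic gene: all 3 coding parts and 2.13% of the 3′ untranslated part were covered, but so were 65.4% of the bases between coding parts, the interval edges set by the peak caller do not resolve exons, and the bounds were set with the coverage already known. No biological explanation beyond these was tested, because the design has no group that differs in HOXA11.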
